A study of Mus musculus with 12 samples.

How the data were processed

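RNA was sequenced from C2C12 cells, an established mouse myoblast line, in 12 libraries that the labels place in 4 groups of 3 biological replicates. Wild-type (WT) cells and cells labelled as Mapk14 knockout (KO) were kept for 5 days in growth medium (GM, with 10% fetal bovine serum) or in differentiation medium (DM, with 2% horse serum). The labels give total RNA, paired-end reads of 150 bp and a single batch date for all libraries, so no batch given in the labels separates the groups. Replicate numbers came from the labels. How many knockout clones were used, how the gene was edited and the strand setting are not given in the sources used here.

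The authors deposited 1 table of whole-number counts per Ensembl gene, with no normalization, for 55416 genes, of which 52083 had a symbol. Per the submitters' processing notes, STAR 2.7.1a, RSEM 1.3.3, R 4.3.1, DESeq2 1.40.2 and the build GRCm39 were used. Which of these tools produced the counts, and the annotation release, are not given in the sources used here. In the table, 4 columns were empty and were not used. Counts of genes that overlap another gene, and of close paralogs such as the Prl2c, Sprr, Saa, H2 and Myh families, depend on the authors' assignment of shared reads, which could not be checked from the counts.

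Library totals ran from 8821669 to 11536396 counts. A count of 3 was taken as the floor that a count of 0 allows, which was 0.26 to 0.346 CPM (edgeR's counts scaled to library size) in single libraries. Intervals (95%) and floors cover counting error only, since reads without molecular identifiers are not independent molecules. For a gene at 0 counts in 1 group the fold was computed against 3 counts over the group.

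Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 13250 genes holding 99.9% of all counts, 20 of them without a symbol. Library sizes were scaled by the trimmed mean of M-values (TMM). One quasi-likelihood model with robust dispersion was fitted to all 12 libraries with a mean for each group, and 5 contrasts were tested 2-sided. These were WT DM against WT GM, KO DM against KO GM, KO GM against WT GM, KO DM against WT DM, and the interaction, which is the response to DM in the KO-labelled cells minus that in WT cells. Adjusted p is the Benjamini-Hochberg value over the 13250 genes of a contrast, and a gene was called below 0.05. A second count required in addition a log2 fold change of at least 1. The words rose and fell are used only of called genes. Changes are given as log2 fold changes ± SE, the SE being the change divided by the square root of the F statistic, and CPM values as mean ± SD of n = 3 libraries.

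A set of 32 gene lists was fixed before the data were examined, as were the samples, contrasts, alternatives and the rule for named genes. The lists were sarcomere, calcium handling and excitation-contraction coupling, neuromuscular junction, myogenic transcription factors, inhibitors of myogenic differentiation and progenitor markers, myoblast fusion and adhesion, muscle energy metabolism, S phase and replication, mitosis, cell cycle exit, p38 MAPK pathway, ERK pathway output, immediate early and AP-1 genes, NF-kB and inflammatory genes, interferon response, extracellular matrix, smooth muscle and TGF-beta genes, IGF pathway, BMP, Wnt and Notch targets, adipogenic markers, bone and cartilage markers, oxidative phosphorylation, mitochondrial-encoded transcripts, glycolysis and hypoxia, cholesterol synthesis, proteolysis and autophagy, p53 targets and apoptosis, ER stress and amino acid response, and markers of macrophages and leukocytes, endothelium, epithelium, and neural and Schwann cells. The 28 lists with at least 5 tested members were tested in each contrast with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. These p values were adjusted over the 140 tests of each kind. Camera used log2 CPM with a prior count of 2. Counts of members that passed are given over all genes tested, and also adjusted over the list alone; where no second count is given it was the same.

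The rule for named genes took Mapk14, the 10 largest rises and 10 largest falls of each contrast, up to 4 members of each gene list described and a fixed panel of muscle and cell cycle genes. The largest changes were taken among called genes with at least 10 CPM in the higher group and no overlap between replicates, leaving out predicted genes and pseudogenes. List members were taken by the size of the change among those called, or, where none was called, the 2 with the highest CPM. The text names part of the genes that the rule gave.

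The alternatives tried were 3 other scalings (median-of-ratios factors, upper-quartile factors and total counts alone), DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter of 1 CPM and 10 counts in 3 libraries, dispersion without robust estimation, fits of only the 6 libraries compared, library sizes without sarcomere and mitochondrial genes, a block for replicate number, and leaving out each library in turn. Leaving out the replicate 3 libraries of both GM groups together was chosen after the data had been seen. Replicate pairs were compared by a chi-square statistic over genes of at least 20 counts in the pair, which was 3.58 to 14.9 per degree of freedom, so no pair matched within counting error.

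The fit was tested on simulated data with 200 changed genes planted, of which 64 (1.5-fold), 65 (2-fold) and 66 (4-fold) were among the 13024 genes that passed the filter. For KO DM against WT DM, 65.6% of genes changed 1.5-fold, 75.4% of those changed 2-fold and 98.5% of those changed 4-fold were found, with 15 unchanged genes called (8.77% of calls). For the interaction the shares were 45.3%, 69.2% and 90.9%, with 6 unchanged genes called (4.29%). In the simulated set tests, a shifted list of 20 genes was found and 0 of 20 unshifted lists were called by camera or fry. The simulated genes were drawn independently of each other, so this cannot test the preset correlation in lists of co-regulated genes. Far fewer genes were planted than were called in the data, so the shares found need not hold there. Gene order along chromosomes, used for 1 observation, came from a GENCODE M21 annotation of build GRCm38, another build than the authors', so no coordinates are given. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.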

Results

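Gene expression was measured by RNA sequencing in 12 libraries of C2C12 mouse myoblasts, 3 each of WT cells in GM, WT cells in DM, KO-labelled cells in GM and KO-labelled cells in DM, all after 5 days. C2C12 myoblasts withdraw from the cell cycle and fuse into myotubes when serum is lowered. Totals were 8821669 to 11536396 counts per library, and 16039 to 16677 genes had a count. The first principal component held 56.1% of the variance and parted GM from DM, and the next held 27.9% and parted the genotype labels.

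**Figure D1:**
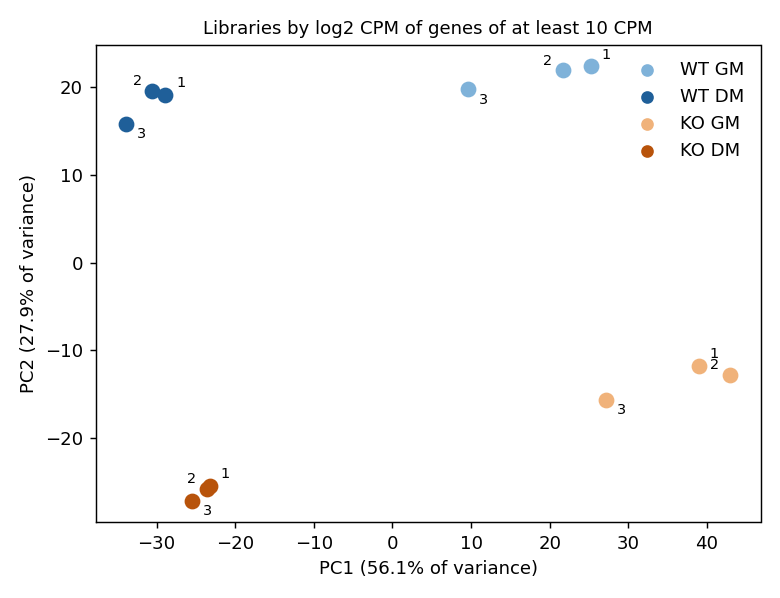
Each point is a library, placed by the first 2 principal components of log2 CPM over 9634 genes of at least 10 CPM; colours give the group and digits the replicate number. The replicate 3 libraries of both GM groups lie nearer to the DM libraries on the first component (9.66 and 27.1) than the other libraries of their group (21.7 and 25.2 in WT, 38.9 and 43 in KO).

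Mapk14 (ENSMUSG00000053436), which encodes p38 alpha and is the gene named in the knockout label, was not lower in the libraries labelled KO. In GM it was at 134 ± 3.58 CPM in the KO-labelled libraries and 124 ± 14 in WT, a change of 0.11 ± 0.08 (adjusted p = 0.35). In DM it was at 89.5 ± 4.67 CPM and 91.3 ± 2.59, a change of -0.03 ± 0.08 (adjusted p = 0.822). Single libraries held 108 to 135 CPM in WT GM, 130 to 137 in KO GM, 88.7 to 93.9 in WT DM and 84.5 to 93.8 in KO DM. The counts thus show no loss of Mapk14 RNA under the label, and they measure neither the protein nor the edited sequence. Since the way the gene was edited is not given, they cannot decide whether the label holds. Every genotype direction below is between libraries by their labels. Of the related kinases, Mapk11 was at 27.7 ± 3.56 and 33 ± 4.8 CPM in KO GM and WT GM (-0.25 ± 0.14, adjusted p = 0.216) and Mapk12 at 20.2 ± 3.77 and 18.4 ± 2.93 (0.13 ± 0.14, adjusted p = 0.589). Mapk13 had 68 counts over all libraries and was not tested.

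**Figure D2:**
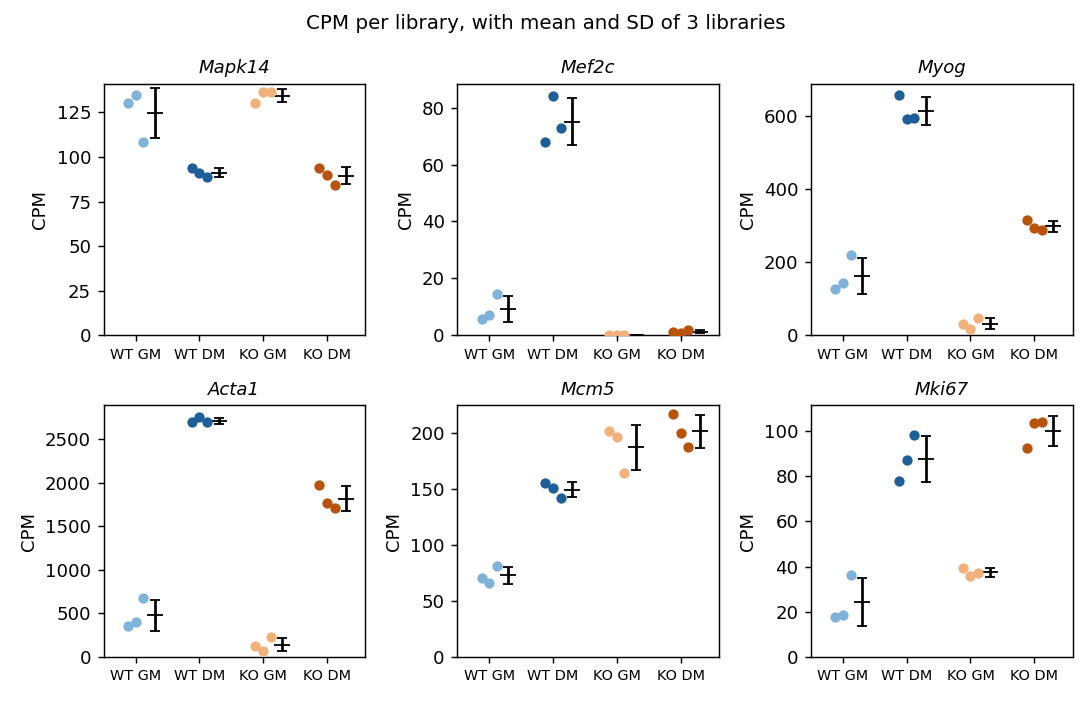
CPM of 6 genes in each library (points, coloured by group), with the mean (tick) and SD (bar) of 3 libraries beside them, on linear axes from 0. Mapk14 lies at 124 and 134 CPM in the GM groups and 91.3 and 89.5 in the DM groups, while Mef2c lies at 75.1 CPM in WT DM and 1.18 in KO DM.

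The response of WT cells to DM was examined first, as the reference for myogenic differentiation. Muscle structural genes were much higher in DM. Myh2, Myh1 and Myh3, which encode myosin heavy chains, rose by 5.65 ± 0.38, 4.69 ± 0.49 and 3.74 ± 0.36, Myh3 from 64.2 ± 32.5 to 856 ± 32.8 CPM. Skeletal actin Acta1 rose from 478 ± 177 to 2713 ± 34.6 CPM (2.51 ± 0.41, adjusted p = 0.00155). All 39 tested members of the sarcomere list rose (median 2.64; set test adjusted p = 3.85e-24, but adjusted p = 0.169 with an estimated correlation).

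Other muscle lists also held mostly risers. In calcium handling, 17 of 19 members rose (median 2.09, adjusted p = 0.156 with an estimated correlation), among them the calcium store protein Casq2 (3.21 ± 0.38). A further member fell when adjusted over the list alone. In the neuromuscular junction list 9 of 11 rose (adjusted p = 0.137 with an estimated correlation), and Chrng, the fetal acetylcholine receptor subunit, rose by 2.07 ± 0.23. Muscle energy metabolism had 11 risers of 15 (adjusted p = 0.137 with an estimated correlation), including muscle creatine kinase Ckm (3.18 ± 0.20). Myoblast fusion and adhesion had 12 risers and 2 fallers of 19 (3 fallers adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), and Mymk, which encodes the fusogen myomaker, rose by 2.65 ± 0.31. Of 13 myogenic transcription factors 8 rose (adjusted p = 0.137 with an estimated correlation): Mef2c by 3.03 ± 0.30, Myog by 1.91 ± 0.31 and Myod1 by 0.28 ± 0.09.

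Cell cycle genes were also higher in DM than in GM. All 24 tested mitosis genes rose (median 1.61, adjusted p = 0.158 with an estimated correlation), as did all 26 of S phase and replication (median 0.81, adjusted p = 0.156 with an estimated correlation). The proliferation marker Mki67 rose from 24.2 ± 10.6 to 87.7 ± 10.2 CPM (1.86 ± 0.23), the cyclin Ccna2 by 1.93 ± 0.19 and the ribonucleotide reductase subunit Rrm1 by 1.07 ± 0.11. In the cell cycle exit list 6 of 14 rose and 4 fell. The inhibitor Cdkn1a (p21) rose by 0.94 ± 0.07 and cyclin D1, Ccnd1, fell by 1.07 ± 0.11. Cholesterol synthesis genes all rose, 20 of 20 (median 1.34, adjusted p = 0.137 with an estimated correlation), with Insig1 at 2.15 ± 0.14 and the farnesyl diphosphate synthase gene Fdps at 1.97 ± 0.10.

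Growth factor outputs and part of the inflammatory genes fell in WT DM. In ERK pathway output 13 of 17 genes fell and 1 rose (median -0.74, adjusted p = 0.177 with an estimated correlation). The ERK phosphatase gene Dusp6 fell by 1.27 ± 0.14, while Spry1 rose by 1.68 ± 0.22. Glycolysis and hypoxia had 18 fallers and 2 risers of 25 (19 fallers adjusted over the list alone, adjusted p = 0.232 with an estimated correlation), including the glucose transporter gene Slc2a1 (-1.01 ± 0.09) and Vegfa (-0.89 ± 0.09). Of 18 NF-kB and inflammatory genes 7 fell and 4 rose (8 fallers adjusted over the list alone, adjusted p = 0.35 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, fell by 2.82 ± 0.13, and the cytokine gene Il6 was at -3.35 ± 0.48. Among 16 immediate early genes 6 fell, such as Nr4a1 (-1.62 ± 0.15), and 4 rose, such as Egr3 (1.53 ± 0.14).

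Extracellular matrix genes rose in 15 of 25 cases (16 adjusted over the list alone; 1 fell, adjusted p = 0.419 with an estimated correlation), among them the collagen gene Col1a1 (1.77 ± 0.25). In the IGF pathway 8 of 15 rose and 3 fell (adjusted p = 0.419 with an estimated correlation). The growth factor gene Igf1 rose by 5.05 ± 0.42, and Igf2 was at 138 ± 13.9 and 126 ± 40 CPM (0.14 ± 0.22, adjusted p = 0.688). Bone and cartilage markers had 1 riser and 4 fallers of 7 (adjusted p = 0.169 with an estimated correlation). Inhibitors of myogenic differentiation had 9 risers and 7 fallers of 19, with the inhibitor Id1 down by -1.58 ± 0.14. Smooth muscle and TGF-beta genes (4 rose, 4 fell of 15; 5 fell adjusted over the list alone), adipogenic markers (1 rose, 3 fell of 7) and p53 targets (6 rose, 7 fell of 20) went both ways. In the p38 MAPK pathway list 1 of 19 rose and 6 fell, with Mapk11 at -0.83 ± 0.14; Mapk12 was at 0.21 ± 0.14 (adjusted p = 0.281), and Mapk14 itself fell by 0.45 ± 0.08 (adjusted p = 1.25e-04). Among the largest changes outside the lists, R3hdml rose by 5.16 ± 0.23, and Ramp3, a receptor partner, Cyp1a1, a xenobiotic-metabolizing enzyme, and Prl2c2 (proliferin, 1 of several near-identical paralogs) fell (-6.03 ± 0.33, -4.81 ± 0.34 and -3.82 ± 0.41).

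By edgeR, 2442 of 13250 genes were higher and 1963 lower in WT DM than in WT GM, 894 and 330 of them at least 2-fold. With total counts alone these were 2178 and 2430, so the larger count turned from higher (55.4% of called genes) to lower (47.3% higher). All 3 libraries of 1 group lay apart from the 3 of the other for every named gene called in this and the next 3 comparisons. The naming rule itself required this of the largest rises and falls, but not of list members or the fixed panel. WT GM replicate 3 held more of several of these transcripts than the other WT GM libraries: Myog was at 220 CPM against 127 and 143, Acta1 at 680 against 351 and 401, and Mki67 at 36.4 against 17.5 and 18.6. Without the replicate 3 libraries of both GM groups the sarcomere list had 39 risers of 39 and a median of 3.09. The call of Myod1 ended without WT GM replicate 3 (adjusted p = 0.0861), both GM replicate 3 libraries (0.0578) or WT DM replicate 2 (0.128; range over alternatives 0.00336 to 0.128). Igf2 was called without WT GM replicate 3 (adjusted p = 0.0411) or both GM replicate 3 libraries (1.75e-04; highest 0.897), and p38 list fallers were 3 without WT GM replicate 2. Median, mean and set test differed in sign for smooth muscle and TGF-beta genes and for p53 targets.

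The same change of medium was compared in the KO-labelled cells, whose Mapk14 RNA was not lower than in WT. Muscle genes rose here too, from lower starting levels. Acta1 rose from 140 ± 78.6 to 1818 ± 140 CPM (3.69 ± 0.43), the light chain gene Myl1 by 4.23 ± 0.39, and the calcium release channel gene Ryr1 by 4.41 ± 0.33 to 108 ± 0.389 CPM. Myog rose from 31.4 ± 14.6 to 299 ± 15 CPM (3.26 ± 0.34). In the sarcomere list 38 of 39 members rose (median 3.47, or 3.43 with genes at 0 counts placed at their bound, adjusted p = 0.17 with an estimated correlation).

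Calcium handling had 18 risers and 1 faller of 19 (adjusted p = 0.156 with an estimated correlation), and myogenic transcription factors 10 risers of 13 (11 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). Myod1 rose by 0.92 ± 0.09. Mef2c went from 0 counts in KO GM to 1.18 ± 0.558 CPM in KO DM, at least 12.6-fold higher (adjusted p = 0.0254), and Myf5 was at 4.97 ± 1.35 and 4.69 ± 0.265 CPM (-0.10 ± 0.20, adjusted p = 0.723). Mymk rose by 3.74 ± 0.35, Ckm from 0.395 ± 0.273 to 6.65 ± 0.591 CPM and the acetylcholine receptor subunit gene Chrnd by 2.54 ± 0.11. The inhibitor Id3 was at 146 ± 11.8 and 156 ± 5.72 CPM (0.10 ± 0.07, adjusted p = 0.313).

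Of the cell cycle lists, mitosis rose in 23 of 24 members (median 1.45, adjusted p = 0.178 with an estimated correlation), with Mki67 at 1.42 ± 0.22 and the cyclin gene Ccnb2 at 2.32 ± 0.24. S phase and replication had 8 risers, such as E2f2 (0.79 ± 0.11) and Rrm2 (0.43 ± 0.08), and 2 fallers among 26. Without KO GM replicate 3 or KO DM replicate 2 there were 5 risers. Cdkn1a rose by 1.19 ± 0.07 and Ccnd1 fell by 1.39 ± 0.12. Cholesterol synthesis rose in 17 of 20 members (1 fell adjusted over the list alone, adjusted p = 0.137 with an estimated correlation), with Insig1 at 1.94 ± 0.14.

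Glycolysis and hypoxia genes fell in 23 of 25 cases (adjusted p = 0.137 with an estimated correlation), among them the oxidoreductase gene Ero1l (-1.62 ± 0.09), while Pdk4, which restrains pyruvate oxidation, rose by 1.62 ± 0.15. ERK pathway output fell in 13 of 17 (adjusted p = 0.156 with an estimated correlation), with Dusp6 at -2.39 ± 0.15 and the transcription factor gene Etv4 at -2.13 ± 0.13. Immediate early genes fell in 10 of 16 (11 adjusted over the list alone; 3 rose, adjusted p = 0.177 with an estimated correlation), including Fosl1 (-1.97 ± 0.12). NF-kB and inflammatory genes went both ways, 7 up and 4 down of 18 (5 down adjusted over the list alone): the acute phase gene Saa3 rose by 2.84 ± 0.32 and the chemokine gene Ccl7 by 2.58 ± 0.11, and Ptgs2 fell by 2.79 ± 0.13. Interferon response genes rose in 15 of 19 (adjusted p = 0.137 with an estimated correlation), among them the immunoproteasome gene Psmb9 (1.96 ± 0.40).

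Extracellular matrix had 20 risers and 4 fallers of 25 (adjusted p = 0.381 with an estimated correlation), with the proteoglycan gene Dcn going from 0.241 ± 0.125 to 5.14 ± 1.1 CPM. BMP, Wnt and Notch targets had 11 risers and 2 fallers of 16 (12 risers adjusted over the list alone, adjusted p = 0.257 with an estimated correlation), including the Notch ligand gene Dll1 (3.18 ± 0.25). Proteolysis and autophagy had 8 risers and 3 fallers of 16, and ER stress 1 riser and 8 fallers of 16. The latter were 4 without KO GM replicate 1 and 5 without KO DM replicate 2, and ER stress risers were 5 without both GM replicate 3 libraries. The largest rises included Igf1 (5.99 ± 0.43), the small GTPase gene Rrad (5.38 ± 0.28) and the Wnt-associated receptor gene Lgr5 (4.62 ± 0.39). The largest falls were in Cyp1a1 (-6.83 ± 0.37), Ramp3 (-6.29 ± 0.29), Sprr1a, 1 of a paralog cluster (-6.21 ± 0.39), and the protease inhibitor gene Serpinb2 (-5.05 ± 0.26). Mapk14 fell by 0.59 ± 0.08 (adjusted p = 3.13e-06).

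By edgeR, 2754 genes were higher and 2627 lower in KO DM than in KO GM, 946 and 447 at least 2-fold. KO GM replicate 3 held Myog at 45.9 CPM against 31.4 and 16.8 and Acta1 at 227 against 122 and 73, and without both GM replicate 3 libraries the sarcomere list had 37 risers of 39. The Mef2c call ended without any of KO GM replicates 1, 2 and 3 or KO DM replicates 1 and 3 (adjusted p = 0.054 to 0.07; range over alternatives 4.18e-06 to 0.07), and Id3 was called only without both GM replicate 3 libraries (0.0257; range 0.0257 to 0.701). Median, mean and set test differed in sign for inhibitors of differentiation, the p38 pathway, adipogenic markers and p53 targets.

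**Figure D3:**
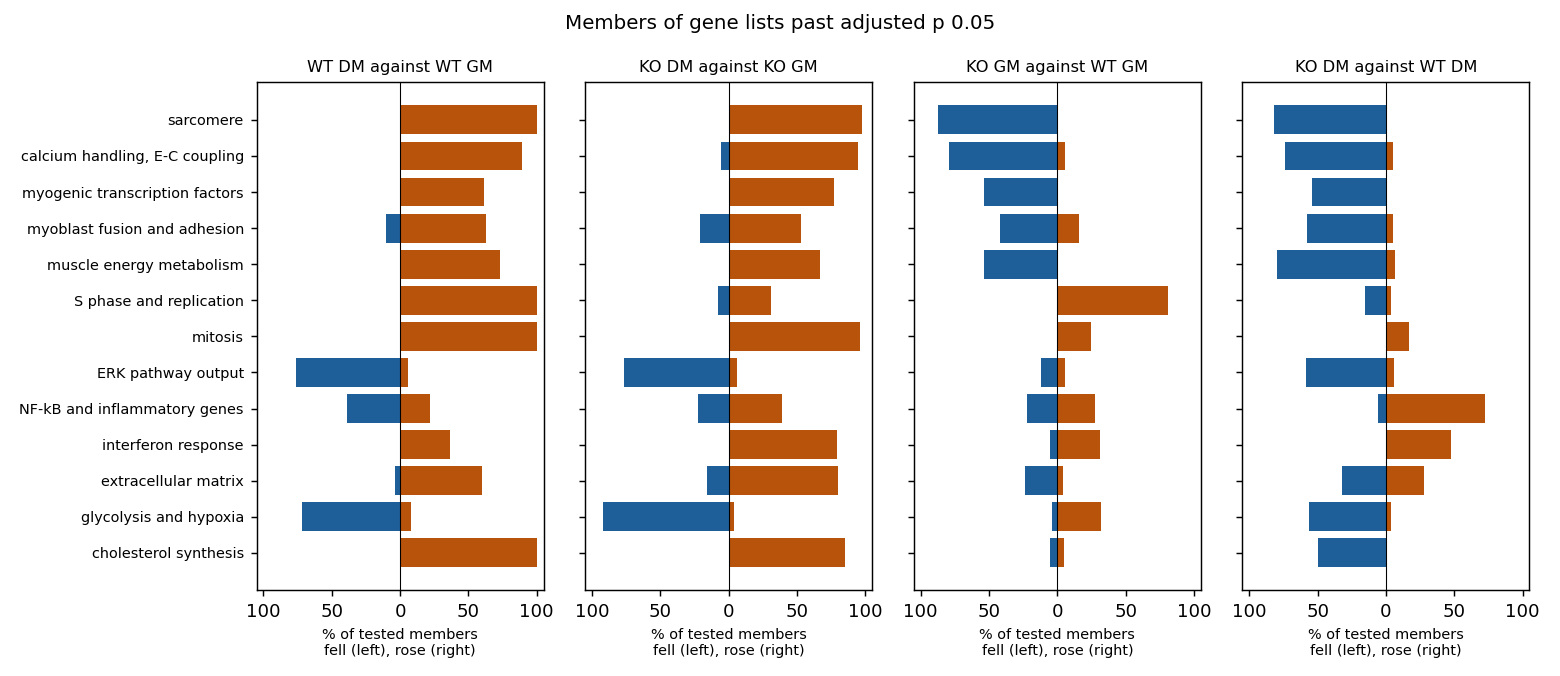
Bars give the percent of tested members of 13 gene lists that rose (right) or fell (left) at adjusted p below 0.05 in the 4 pairwise comparisons. The sarcomere list rose in DM in both genotypes (39 and 38 of 39) and fell in the KO-labelled libraries in both media (34 and 32 of 39).

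In GM, where cells were also kept for 5 days, the libraries labelled KO differed from WT in muscle and replication genes, although not in Mapk14 RNA. Mef2c, a myogenic transcription factor gene, had 0 counts in all 3 KO GM libraries against 9.18 ± 4.73 CPM in WT GM, at least 99.2-fold lower. Myog fell from 163 ± 49.5 to 31.4 ± 14.6 CPM (-2.38 ± 0.34), Myf5 by 1.90 ± 0.17 and Myod1 by 0.97 ± 0.09. Of the sarcomere list 34 of 39 members fell (35 adjusted over the list alone; median -2.13, adjusted p = 0.169 with an estimated correlation). Replication genes were higher: 21 of 26 rose (23 adjusted over the list alone; median 0.62, adjusted p = 0.169 with an estimated correlation), including the helicase subunit gene Mcm5 from 72.7 ± 7.78 to 187 ± 20.1 CPM (1.36 ± 0.09) and the licensing factor gene Cdc6 (1.17 ± 0.10).

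Within the muscle lists, Myl1 fell by 4.01 ± 0.39, Myh3 by 3.85 ± 0.46 and Acta1 by 1.77 ± 0.40 (adjusted p = 0.015). Calcium handling had 15 fallers and 1 riser of 19 (2 risers adjusted over the list alone, adjusted p = 0.177 with an estimated correlation), Casq1 falling by 2.44 ± 0.36. Neuromuscular junction genes fell in 7 of 11 (adjusted p = 0.177 with an estimated correlation), such as Chrnd (-1.84 ± 0.12), and 1 rose, the acetylcholinesterase gene Ache (2.47 ± 0.31). Myogenic transcription factors fell in 7 of 13 (8 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). Fusion and adhesion had 8 fallers and 3 risers of 19 (9 and 4 adjusted over the list alone, adjusted p = 0.239 with an estimated correlation), with Tmem182 at -2.97 ± 0.20 and Mymk at -1.81 ± 0.35. Muscle energy metabolism fell in 8 of 15 (adjusted p = 0.137 with an estimated correlation), with Ckm at -3.05 ± 0.37.

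Mitosis genes rose in 6 of 24 (adjusted p = 0.54 with an estimated correlation), among them the topoisomerase gene Top2a (0.77 ± 0.17). There were 12 without WT GM replicate 3 and 3 without WT GM replicate 2 or KO GM replicate 1. Mki67 was at 37.5 ± 1.89 and 24.2 ± 10.6 CPM (0.63 ± 0.24, adjusted p = 0.106), and was called without WT GM replicate 3 (adjusted p = 1.46e-07), without both GM replicate 3 libraries (1.49e-08), with limma-voom (0.0121), without robust dispersion (0.0265) and with a block for replicate number (0.0477; highest 0.263). Cdkn1a fell by 0.58 ± 0.07. In the p38 MAPK pathway list 5 of 19 fell and 0 rose by edgeR (6 fell adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). The phosphatase gene Dusp1 fell by 1.12 ± 0.11 and the kinase gene Mknk2 by 0.70 ± 0.08. Smooth muscle and TGF-beta genes fell in 6 of 15 (7 adjusted over the list alone, adjusted p = 0.142 with an estimated correlation), with Ccn2 at -1.71 ± 0.10. In the IGF pathway 6 of 15 fell and 3 rose: the binding protein gene Igfbp4 fell by 3.30 ± 0.24 and Igf2 by 1.89 ± 0.24.

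Interferon response genes rose in 6 of 19 and 1 fell (2 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation), with the class I antigen gene H2-K1 at 1.71 ± 0.09 and the immunoproteasome gene Psmb8 at 2.65 ± 0.34. The Wnt target Axin2 rose by 1.87 ± 0.16 among BMP, Wnt and Notch targets, of which 4 rose and 3 fell of 16. Extracellular matrix had 6 fallers and 1 riser of 25, with Dcn at -5.93 ± 0.34 and the basement membrane collagen gene Col4a1 at -1.94 ± 0.18. Fallers were 11 without KO GM replicate 3. Inhibitors of differentiation and progenitor markers had 8 fallers and 2 risers of 19 (9 fallers adjusted over the list alone, adjusted p = 0.169 with an estimated correlation): the Notch target Heyl, with 0 counts in KO GM, was at least 19.5-fold lower, and the progenitor marker Cd34 rose by 0.85 ± 0.08. Adipogenic markers fell in 4 of 7 (adjusted p = 0.173 with an estimated correlation), including the lipase gene Lpl (-3.38 ± 0.44). Glycolysis and hypoxia had 8 risers and 1 faller of 25 (10 risers adjusted over the list alone, 5 without KO GM replicate 2, adjusted p = 0.417 with an estimated correlation), with Ndrg1 at 0.56 ± 0.08. Nuclear-encoded oxidative phosphorylation had 1 faller of 22, the complex I subunit gene Ndufb8 (-0.26 ± 0.07).

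Genes near absence in KO GM included Mgam, an intestinal-type glucosidase gene, at a ratio of 445 (95% counting interval 123 to 3683) lower, the lysyl oxidase-like gene Loxl2 (-7.92 ± 0.27) and the neurofilament gene Nefl (-7.60 ± 0.35). The largest rises included the signalling ligand genes Gdf6 (4.36 ± 0.41) and Wnt5a (3.66 ± 0.15) and the receptor gene Gpr141 (3.29 ± 0.25). By edgeR, 1330 genes were higher and 1410 lower in KO GM than in WT GM, 202 and 577 at least 2-fold. The Acta1 call ended without KO GM replicate 1 (adjusted p = 0.0576; range 9.21e-05 to 0.127) and that of Ndufb8 without WT GM replicate 1 (0.0645; range 0.00377 to 0.0645). Fits of only these 6 libraries gave adjusted p = 0.127 for Acta1 and 0.0754 for Mymk, which is the highest of the alternatives of each, 22 sarcomere fallers of 33 tested, and 864 genes higher. Without both GM replicate 3 libraries, 35 of 39 sarcomere members and 13 of 25 matrix members fell, and 11 of 24 mitosis members rose. Median, mean and set test differed in sign for ERK pathway output (1 rose, 2 fell of 17), proteolysis and p53 targets.

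In DM, the KO-labelled libraries were compared with WT to ask how far differentiation differed after 5 days, again with no difference called in Mapk14 RNA. Several muscle genes were much lower: Myh3 fell from 856 ± 32.8 to 64.8 ± 5.65 CPM (-3.72 ± 0.36), the cardiac actin gene Actc1 from 445 ± 12.1 to 27.4 ± 4.72 (-4.02 ± 0.33) and slow myosin Myh7 was at -4.28 ± 0.34. Mef2c fell from 75.1 ± 8.3 to 1.18 ± 0.558 CPM (-5.98 ± 0.41). Skeletal actin Acta1 was at 1818 ± 140 against 2713 ± 34.6 CPM (-0.58 ± 0.38, adjusted p = 0.308). H2-K1, a class I antigen gene of the interferon response list, rose from 35.2 ± 2.28 to 200 ± 11.3 CPM (2.51 ± 0.09).

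The sarcomere list had 32 fallers of 39 (36 adjusted over the list alone; median -1.54, adjusted p = 0.247 with an estimated correlation). Calcium handling had 14 fallers and 1 riser of 19 (16 and 2 adjusted over the list alone, adjusted p = 0.319 with an estimated correlation): Casq1 fell by 4.14 ± 0.24 and the junctional protein gene Trdn rose by 2.10 ± 0.21. Muscle energy metabolism had 12 fallers and 1 riser of 15 (adjusted p = 0.137 with an estimated correlation), with Ckm at -2.23 ± 0.19. Fusion and adhesion had 11 fallers and 1 riser of 19 (adjusted p = 0.156 with an estimated correlation). Tmem182 fell by 2.02 ± 0.15, and Mymk was at 229 ± 17 against 379 ± 13.7 CPM (-0.73 ± 0.29, adjusted p = 0.0965). Myogenic transcription factors fell in 7 of 13 (1 rose adjusted over the list alone, adjusted p = 0.177 with an estimated correlation): Myf5 by 2.50 ± 0.17, Myog by 1.04 ± 0.31 (adjusted p = 0.0325) and Myod1 by 0.33 ± 0.09.

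NF-kB and inflammatory genes rose in 13 of 18 and 1 fell (2 adjusted over the list alone; median 0.76, adjusted p = 0.137 with an estimated correlation). Saa3 rose by 4.57 ± 0.40, the iron-binding lipocalin gene Lcn2 by 3.07 ± 0.49 and the alarmin gene Il33 by 1.57 ± 0.11. Of 4 macrophage and leukocyte markers 2 rose as well. Interferon response genes rose in 9 of 19 (1 fell adjusted over the list alone, adjusted p = 0.137 with an estimated correlation), including the peptide transporter gene Tap1 (1.56 ± 0.14). BMP, Wnt and Notch targets rose in 10 of 16 (1 fell adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), with Axin2 at 1.44 ± 0.14 and the Wnt deacylase gene Notum at 1.78 ± 0.18. Inhibitors of differentiation had 10 fallers and 3 risers of 19 (11 fallers adjusted over the list alone, adjusted p = 0.287 with an estimated correlation): the Notch targets Heyl and Hey1 fell by 3.75 ± 0.29 and 3.24 ± 0.25, and Id3 rose by 0.56 ± 0.08.

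ERK pathway output fell in 10 of 17 (1 rose; 11 fell adjusted over the list alone, adjusted p = 0.369 with an estimated correlation), with Etv4 at -1.33 ± 0.13. Of immediate early genes 5 fell, such as Egr3 (-2.12 ± 0.15), and 3 rose of 16. Smooth muscle and TGF-beta genes fell in 10 of 15 and 1 rose (adjusted p = 0.156 with an estimated correlation), with the calponin gene Cnn1 at -4.29 ± 0.34, Tagln at -1.07 ± 0.10 and Ccn2 at -1.84 ± 0.10. Cholesterol synthesis fell in 10 of 20 (13 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), with the sterol reductase gene Dhcr7 at -1.09 ± 0.15. Glycolysis and hypoxia fell in 14 of 25 and 1 rose (17 fell adjusted over the list alone, adjusted p = 0.344 with an estimated correlation): the phosphofructokinase gene Pfkp fell by 0.95 ± 0.09 and Pdk4 rose by 1.00 ± 0.15. Its fallers were 9, 7, 8 and 6 without WT DM replicate 2, WT DM replicate 3, KO DM replicate 2 and KO DM replicate 3. In the p38 MAPK pathway list 7 of 19 fell (8 adjusted over the list alone; 4 without WT DM replicate 2 or KO DM replicate 1, adjusted p = 0.156 with an estimated correlation), with the phosphatase gene Dusp10 at -1.26 ± 0.10 and Mknk2 at -0.81 ± 0.08.

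Of p53 targets 2 rose and 2 fell of 20, the apoptosis genes Fas (1.31 ± 0.17) and Pmaip1 (-4.13 ± 0.25) among them. In the IGF pathway 3 rose (5 with a block for replicate number), with the binding protein gene Igfbp3 at 2.30 ± 0.10, and 6 fell of 15. Mitochondrial-encoded transcripts had 1 riser, mt-Atp8 (0.79 ± 0.25), and 1 faller, mt-Nd1 (-0.23 ± 0.09), of 13. Nefl, with 0 counts in KO DM, was at least 343-fold lower, and Loxl2 and the tetraspanin gene Tspan7 were lower at ratios of 988 (95% counting interval 273 to 8164) and 791 (142 to 31286). The transcription cofactor gene Vgll2 fell by 6.61 ± 0.36. The largest rises included the pyrimidine-degrading enzyme gene Dpyd (5.29 ± 0.50), the matrix protease gene Mmp3 (4.61 ± 0.28), Pappa2, which cleaves IGF binding proteins (3.34 ± 0.29), and Gdf6 (3.24 ± 0.23). Mki67 was at 100 ± 6.6 and 87.7 ± 10.2 CPM (0.19 ± 0.21, adjusted p = 0.556).

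By edgeR, 1802 genes were higher and 2312 lower in KO DM than in WT DM, 385 and 710 at least 2-fold. With total counts alone these were 2134 and 1968, so the larger count turned from lower (43.8% higher) to higher (52.0%). Dispersion was estimated per gene over all 12 libraries, those in GM included. Single libraries held Myog at 592 to 658 CPM in WT DM and 287 to 316 in KO DM. Acta1 was at 2692 to 2753 CPM in WT DM and 1707 to 1976 in KO DM, so neither gene overlapped between the groups. Without both GM replicate 3 libraries, 39 of 39 sarcomere members fell, Acta1 with them (adjusted p = 0.0433), which was also called in fits of only these 6 libraries (3.14e-09; range over alternatives 3.14e-09 to 0.478). Myog lost its call without any 1 of the 6 DM libraries (adjusted p = 0.0744 to 0.0991) and with no filter (0.0559; range 1.67e-14 to 0.0991), and Myod1 without WT DM replicate 2 or KO DM replicate 3 (0.0593 and 0.0571; range 3.21e-04 to 0.0593). The call of mt-Nd1 (adjusted p = 0.0411) ended in 13 of 23 alternatives, the 3 other scalings and DESeq2 among them (range 0.00368 to 0.236), and that of mt-Atp8 without WT DM replicate 1 or KO DM replicate 1 (0.0894 and 0.0607; range 0.00306 to 0.0894). Mymk was called in 5 alternatives: without KO GM replicate 3 (0.0244), without both GM replicate 3 libraries (5.10e-10), with limma-voom (0.00251), without robust dispersion (0.0141) and in fits of only these 6 libraries (1.37e-10; highest 0.226). Mki67 was called without WT GM replicate 3 (0.0496), without both GM replicate 3 libraries (0.0310) and in those fits (0.0306; highest 0.758). Median, mean and set test differed in sign for cell cycle exit, extracellular matrix, mitochondrial-encoded transcripts, proteolysis and p53 targets. Of 1330 genes higher in KO GM than in WT GM, 624 were also higher in KO DM than in WT DM (181 by chance) and 61 lower. Of 1410 lower in GM, 909 were also lower in DM (246 by chance) and 33 higher. Across genes the differences in the 2 media, which share no library, had r = 0.746 and rho = 0.458; genes are not independent replicates.

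The interaction tested directly whether the response to DM differed between the genotype labels. Replication genes were mostly lower in the interaction, 19 of 26 members of S phase and replication (22 adjusted over the list alone; median -0.70, adjusted p = 0.156 with an estimated correlation). Mcm5 went from 72.7 ± 7.78 to 149 ± 6.7 CPM in WT and from 187 ± 20.1 to 202 ± 14.7 in the KO-labelled cells (-0.93 ± 0.12), and Cdc6 (-1.29 ± 0.14), Mcm3 (-1.02 ± 0.12) and the cyclin E gene Ccne2 (-1.12 ± 0.20) differed the same way. Of the 26 members, 21 rose and 0 fell in KO GM against WT GM, while 1 rose and 4 fell in KO DM against WT DM. Of 18 NF-kB and inflammatory genes 7 were higher and 1 lower in the interaction (13 and 2 adjusted over the list alone; median 0.81, adjusted p = 0.137 with an estimated correlation), with Ccl7 at 1.94 ± 0.16, Ccl2 at 1.36 ± 0.27 and Saa3 at 2.87 ± 0.71 (adjusted p = 0.0179). Of 4 macrophage and leukocyte markers 2 were higher as well (1 without both GM replicate 3 libraries).

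Sarcomere genes rose in both genotypes, and 3 of 39 differed, all higher (median 0.69, adjusted p = 0.706 with an estimated correlation). There were 12 without KO GM replicate 3, 21 without both GM replicate 3 libraries, 7 with limma-voom and 6 without robust dispersion. The 3 were Myl1 (2.02 ± 0.50, adjusted p = 0.0423), the methyltransferase gene Smyd1 (1.45 ± 0.28) and the desmin gene Des (0.52 ± 0.14, adjusted p = 0.0209). In the neuromuscular junction list 3 of 11 were higher (5 higher and 1 lower adjusted over the list alone; 5 higher without KO GM replicate 3 and 6 without both GM replicate 3 libraries, adjusted p = 0.344 with an estimated correlation), namely Chrnd (0.94 ± 0.15), the receptor kinase gene Musk (1.23 ± 0.27) and Dok7, whose product activates that kinase (0.77 ± 0.20). Myod1 was higher by 0.64 ± 0.12 and Acta1 at 1.19 ± 0.55 (adjusted p = 0.24). In mitosis 1 of 24 members was lower, Cdk1 (-0.50 ± 0.14, adjusted p = 0.0275), against 6 without WT GM replicate 3 or both GM replicate 3 libraries, and Mki67 was at -0.44 ± 0.32 (adjusted p = 0.467).

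ERK pathway output had 5 lower and 1 higher of 17 (9 lower adjusted over the list alone, 3 without WT DM replicate 2 or KO GM replicate 2 or with total counts alone, and 9 with a block for replicate number, adjusted p = 0.293 with an estimated correlation), with Dusp6 at -1.12 ± 0.20, Etv4 at -1.18 ± 0.17 and Spry2 at 0.64 ± 0.12. The immediate early genes Egr3 (-2.49 ± 0.21) and Egr1 (-1.32 ± 0.12) were lower, in a list with 4 higher and 4 lower of 16 (8 lower adjusted over the list alone). Glycolysis and hypoxia had 13 lower and 1 higher of 25 (18 lower adjusted over the list alone, 8 without WT DM replicate 2 and 7 without KO DM replicate 3, adjusted p = 0.156 with an estimated correlation), with Ero1l at -1.01 ± 0.13 and Pdk4 at 0.90 ± 0.22. Cholesterol synthesis had 7 lower of 20 (12 adjusted over the list alone, 4 without WT DM replicate 3, adjusted p = 0.152 with an estimated correlation), with the sterol carrier gene Stard4 at -1.02 ± 0.21.

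Interferon response had 3 higher of 19 (6 adjusted over the list alone or without WT DM replicate 3, 7 without both GM replicate 3 libraries, adjusted p = 0.185 with an estimated correlation), namely H2-K1 (0.80 ± 0.12), Tap1 (0.89 ± 0.19) and the class I light chain gene B2m (0.46 ± 0.12). The IGF pathway had 3 higher and 1 lower of 15 (adjusted p = 0.419 with an estimated correlation), with the binding protein gene Igfbp5 at 1.68 ± 0.21. BMP, Wnt and Notch targets had 3 higher and 1 lower of 16 (7 higher without KO GM replicate 3 and 6 without both GM replicate 3 libraries, adjusted p = 0.402 with an estimated correlation). Id3 was higher by 0.97 ± 0.11 and the smooth muscle gene Tagln lower by -1.24 ± 0.14. The largest differences were in Smpx, a striated muscle gene (4.29 ± 0.88), the receptor gene Npy1r (3.11 ± 0.30), Rrad (2.91 ± 0.39), Sprr1a (-5.19 ± 0.50) and Afap1l1 (-3.11 ± 0.37). Mapk14 was at -0.14 ± 0.11 (adjusted p = 0.483).

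By edgeR, 478 genes were higher and 696 lower in the interaction (40.7% higher), 131 and 137 at least 2-fold. With total counts alone these were 683 and 498 (57.8% higher). Genes higher numbered 293 without WT DM replicate 2 and 969 without KO GM replicate 3, genes lower 400 and 951, and without both GM replicate 3 libraries the counts were 1373 and 1336. Calls that ended were Saa3 without WT GM replicate 3 (adjusted p = 0.0722; range over alternatives 3.01e-06 to 0.0722), Des without KO GM replicate 1, KO GM replicate 2 or KO DM replicate 1 (0.0526 to 0.054; range 7.28e-06 to 0.054), and Myl1 without any of 9 libraries, all but WT GM replicates 1 and 3 and KO GM replicate 3 (0.0645 to 0.099), or with no filter (0.0542; range 6.99e-04 to 0.099). Cdk1 lost its call without any of 8, all but WT GM replicate 3, WT DM replicate 1 and KO GM replicates 2 and 3 (0.0538 to 0.108; range 0.0014 to 0.108). Dok7 lost its call without WT GM replicate 2 or KO GM replicate 1 (0.0546 and 0.0562; range 0.00249 to 0.0562), and B2m without WT DM replicate 2, KO GM replicate 2 or KO DM replicate 3 (0.0606 to 0.0671; range 7.87e-04 to 0.0671). Mki67 was called without WT GM replicate 3 (2.94e-04) or both GM replicate 3 libraries (4.71e-05; highest 0.729). Acta1 was called without KO GM replicate 3 (0.0341), without both GM replicate 3 libraries (0.0153) and with limma-voom (0.0426; highest 0.392). Median, mean and set test differed in sign for inhibitors of differentiation, fusion and adhesion, and muscle energy metabolism.

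Most of the WT response was shared. Of 2442 genes that rose in WT, 1599 (65.5%) also rose in the KO-labelled cells (508 by chance) and 55 fell. Of 1963 that fell, 1292 (65.8%) also fell (389 by chance) and 32 rose. Among 894 genes that rose at least 2-fold in WT, 728 also rose in the KO-labelled cells. By the interaction, 86 of the 894 responded less and 45 more. Among 330 that fell at least 2-fold in WT, 242 also fell, and 40 of the 330 responded less and 27 more. Across 13250 genes the responses, which share no library, had r = 0.738, rho = 0.623 and a slope of 0.855, with genes not being independent replicates. With DESeq2 r was 0.37 and the slope 0.386, and with no filter 0.293 and 0.295. Both settings include genes of few counts that the filter removes. With limma-voom, run on the 13250 genes, r and slope stayed within 0.1 of 0.738 and 0.855.

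**Figure D4:**
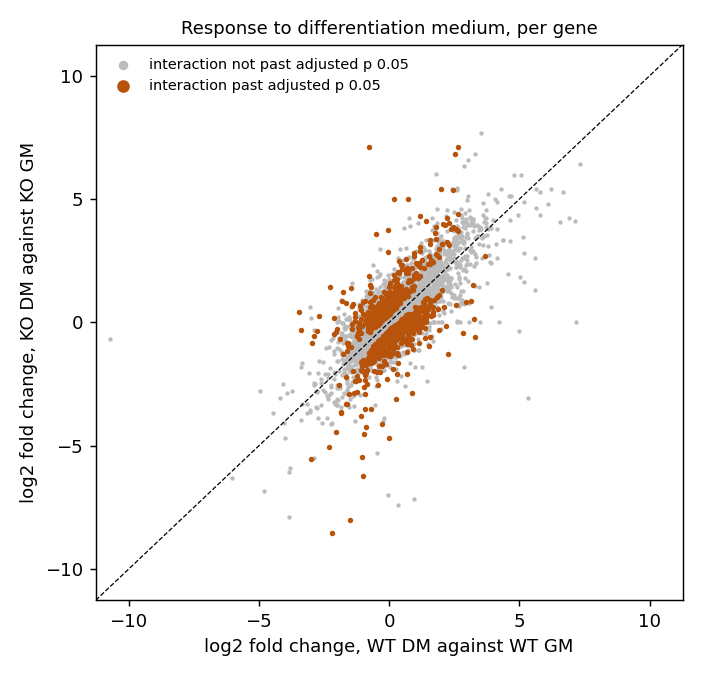
Each point is 1 of 13250 tested genes, with its log2 fold change in WT DM against WT GM (x axis) and in KO DM against KO GM (y axis); orange points passed adjusted p 0.05 in the interaction, and the dashed line marks equal responses. The responses had a slope of 0.855, and 1174 genes differed.

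Set tests were called in 70 of 140 cases by camera with the preset correlation and in 89 by fry; with an estimated correlation the count was 0, with 38 of 140 at an unadjusted p under 0.05 and a lowest adjusted p of 0.137. Lists of other cell types had too few expressed members for a set test, with 4 macrophage and leukocyte, 2 endothelial, 2 epithelial and 4 neural and Schwann cell markers tested of 10 listed each. In KO DM against WT DM, 2 of the 4 macrophage markers rose, the lysozyme gene Lyz2 (2.10 ± 0.26) and the endotoxin co-receptor gene Cd14 (1.19 ± 0.16). The endothelial marker Flt1, a VEGF receptor gene, fell by 2.77 ± 0.49. Of the keratin genes, Krt14 rose by 2.32 ± 0.28 and Krt19 fell by 4.21 ± 0.39. Of the 4 neural markers 3 fell: the microtubule genes Map2 (-4.29 ± 0.24), Tubb3 (-3.10 ± 0.13) and Stmn2 (-0.35 ± 0.10). The Stmn2 call ended without WT DM replicate 2 or KO DM replicate 2 (adjusted p = 0.0785 and 0.0592; range 0.0019 to 0.0785). In the other comparisons, macrophage markers had 2 fallers of 4 in WT DM against WT GM, 1 riser and 1 faller in KO DM against KO GM, 1 riser in KO GM against WT GM and 2 higher in the interaction. Neural markers had 1 riser of 4 in WT DM against WT GM, 1 riser and 2 fallers in KO DM against KO GM and in KO GM against WT GM, and 2 lower in the interaction. Of 2 epithelial markers 1 rose and 1 fell in each pairwise comparison and 0 were called in the interaction (1 lower adjusted over the list alone). Without both GM replicate 3 libraries 1 was higher and 1 lower there, and 0 rose in KO GM against WT GM. Of 2 endothelial markers 1 fell in KO GM against WT GM and 0 were called in the other 3.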

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

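The splits and regroupings below were planned before the counts of genes were seen; no test in this part was chosen after its result. The results here were taken because the response to DM differed between the genotype labels by the interaction, and they are given as values without explanation. Mapk14 RNA was not lower in the libraries labelled KO, so each difference is between libraries by their labels.

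In the interaction 478 genes were higher and 696 lower. Of 200 possible regroupings of the genotype labels within each medium, 60 were drawn, the real one included. In 1 of these 60 were as many genes called as the real 1174. The highest other split gave 1090; it kept the genotypes apart in DM and mixed them in GM, and 968 came from another of that kind. Regrouping also breaks up the difference between the genotypes within a medium, so this count does not test the interaction alone, and nothing is concluded from it about chance. At an unadjusted p under 0.05 the real grouping had 3119 genes and the highest other 3440. For the pairwise comparisons only 10 splits of 6 libraries exist, too few for a share under 0.05, and in each the real split was the 1 with the most calls. The real counts were 4405 for WT DM against WT GM, 5381 for KO DM against KO GM, 2740 for KO GM against WT GM and 4114 for KO DM against WT DM; edgeR called 0 genes in every other split. At an unadjusted p under 0.05 those other splits had up to 1414, 822, 1602 and 415 genes, and no other tool was run on them. Every other split mixes libraries of both groups, so the group difference adds to the spread, and nothing is concluded from the 0.

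List medians in the interaction were -0.70 for S phase and replication, 0.81 for NF-kB and inflammatory genes, 0.69 for sarcomere, 0.25 for neuromuscular junction, 0.31 for interferon response, 0.087 for the IGF pathway, 0.25 for BMP, Wnt and Notch targets, -0.42 for ERK pathway output, -0.41 for glycolysis and hypoxia and -0.33 for cholesterol synthesis. These were called with the preset correlation and not with an estimated one (adjusted p = 0.137 to 0.706).

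Among genes lower in the interaction, the replication and division genes Cdc6, Mcm3, Mcm5, Ccne2 and Cdk1 differed by -1.29, -1.02, -0.93, -1.12 and -0.50. Stard4 differed by -1.02 and Ero1l by -1.01. Egr3, Egr1, Dusp6 and Etv4 differed by -2.49, -1.32, -1.12 and -1.18. Sprr1a, Afap1l1 and Tagln differed by -5.19, -3.11 and -1.24.

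Genes higher in the interaction included Saa3, Ccl7, Ccl2, H2-K1, Tap1 and B2m (2.87, 1.94, 1.36, 0.80, 0.89 and 0.46). Muscle genes were Smpx, Myl1, Smyd1, Des, Chrnd, Musk, Dok7 and Myod1 (4.29, 2.02, 1.45, 0.52, 0.94, 1.23, 0.77 and 0.64). The others were Npy1r, Rrad, Igfbp5, Id3, Spry2 and Pdk4 (3.11, 2.91, 1.68, 0.97, 0.64 and 0.90). Each value is a difference between log2 changes and not a level of expression. Of 39 sarcomere members, 34 fell in KO GM against WT GM and 32 in KO DM against WT DM.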

How the results depend on the processing

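Leaving out the replicate 3 libraries of both GM groups together was chosen after the data had been seen; the other alternatives were planned. Of 204 results for named genes, 24 changed their side of the threshold in at least 1 of up to 24 alternatives run on them, and the others kept side and direction in all. Over 4840 pairs of result and alternative, 4752 were the same, 65 lost a call, 23 gained one and 0 reversed. The 3 other scalings, DESeq2 and the stricter filter each changed 1 of the 204, mt-Nd1 in KO DM against WT DM. Simulated 1.5-fold changes were found in 65.6% of cases for KO DM against WT DM and 45.3% for the interaction.

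The following counts and values moved, and where no cause is named the cause was not tested. The correlation of the responses was 0.37 with DESeq2 and 0.293 with no filter, with slopes of 0.386 and 0.295, and both settings include genes of few counts that the filter removes. At a mean of at least 10 CPM the slope was 0.959. Genes higher in KO GM than in WT GM numbered 864 in the fit of 6 libraries. For KO DM against WT DM such a fit gave 2431 genes higher and 2508 lower, more than the 1802 and 2312 of the main fit. Fewer samples alone therefore do not account for the 864. With an estimated correlation 0 set tests were called. Without both GM replicate 3 libraries the interaction had 1373 genes higher and 1336 lower.

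Leaving out 1 library at a time gave 293 (WT DM replicate 2) to 969 (KO GM replicate 3) genes higher in the interaction and 400 (WT DM replicate 2) to 951 (KO GM replicate 3) lower. Genes higher were also moved by over 1.5 times without WT GM replicate 3 (738), KO GM replicate 1 (307) and KO GM replicate 2 (304). Genes lower moved so without WT GM replicate 2 (428), KO GM replicate 1 (428), KO GM replicate 2 (437) and KO DM replicates 1, 2 and 3 (414, 459 and 460). The slope ran from 0.719 (WT GM replicate 3) to 0.904 (KO GM replicate 3). Mapk14 ran from 0.02 to 0.17 in KO GM against WT GM and from -0.04 to 0.02 in KO DM against WT DM, never called.

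With a block for replicate number the interaction had 666 genes higher and 921 lower, and all 15 main counts and values kept their side or stayed within 1.5 times. Of named genes only Mki67 in KO GM against WT GM gained a call (adjusted p = 0.0477; range over its alternatives 1.49e-08 to 0.263). The labels share only a number. After removing group means, libraries correlated best with their own number in most cases but not in all. This is a hint from the data of a link between libraries of the same number. Their correlations were 0.315 to 0.34 between WT GM and KO DM and 0.104 to 0.276 between WT DM and KO GM. They were 0.0901 to 0.147 between WT GM and WT DM and 0.0539 to 0.118 between the DM groups. In all these pairs of groups each library matched its own number best. So did replicates 2 and 3 of WT GM and KO GM (0.127 and 0.327). Own numbers did not match best for replicate 1 of WT GM and KO GM (-0.129) or for any replicate of KO GM and KO DM (-0.275 to 0.0252).

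Of 140 set tests of gene lists, 70 lost their call with an estimated correlation, and fry gained 23 and lost 4. No filter gained 9, leaving out both GM replicate 3 libraries gained 8 and lost 1, and total counts alone gained 1 and lost 5. Leaving out 1 library lost up to 6 (WT GM replicate 3) and gained up to 7 (KO GM replicate 3). Set tests were not run under DESeq2, limma-voom, the fit of 6 libraries and library sizes without sarcomere and mitochondrial genes.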

Other observations

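In this part all tests of the neighbouring genes, the tests of equal loss and of cell populations for muscle genes, and the test of crowding for cell cycle genes were chosen after the results were seen, and leaving out the replicate 3 libraries of GM after the data had been seen; those of scaling were planned.

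A run of neighbouring genes on chromosome 8 was higher in the libraries labelled KO, in both media. The stretch held 45 tested genes from Heatr3 to Ndrg4, in the gene order of build GRCm38, with a median difference of 0.58 in GM and 0.64 in DM (1.55-fold). Of these genes, chosen after their values were seen, 38 were called higher in GM and 40 in DM, and 0 were called lower by edgeR in either. Each KO-labelled library stood at 0.56 to 0.64 against the WT mean and each WT library at -0.04 to 0.04, while the medians of all genes were 0.00 and -0.02. Chance order of genes was argued against by 0 of 1000 shuffles with a running median over 41 genes as high, the highest shuffle reaching 0.22; the lowest running median, -0.23 on chromosome 1, was also reached by 0 shuffles. Without its 10 largest differences in GM the stretch held 35 genes, of which 91.4% (32) lay above the all-gene median in DM. But the stretch was bounded by a running median in GM, so this largely restates its choice. Shared regulation of neighbouring genes stays open. An extra DNA copy of the stretch may account for the 0.64, which lies near the 1.5-fold that 3 copies against 2 would give. No DNA was measured, and the number of copies in the WT cells is not known here. Medians in GM and DM were also 0.20 and 0.20 for chromosome 11 (809 genes), 0.11 and 0.10 for chromosome 9, -0.07 and -0.16 for chromosome 10 and -0.08 and -0.12 for chromosome 19, given without explanation.

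Mitosis genes were higher after 5 days in DM than after 5 days in GM in both genotypes, although cells leave the cycle as they differentiate. The choice among scalings was argued against, since the lowest mitosis median over both genotypes and 3 other scalings was 1.46. Total counts alone shifted the changes by a median of only -0.044 in WT and 0.02 in the KO-labelled cells, so this could hardly have turned out otherwise. None of these scalings can show a change in total RNA per cell. Without the replicate 3 libraries of GM, 24 of 24 members rose in WT and 23 of 24 in the KO-labelled cells. The WT median was then 1.84 against 1.61 with them. These libraries lay nearer to DM, so leaving them out was likely to keep or widen the difference. Nothing is concluded from this about its cause. Fewer cycling cells in GM cultures that had grown crowded over 5 days could give the WT median of 1.61; that cannot be told apart from an effect of DM, because the tables hold no measure of density. The biological explanation, a response to the medium, stays open and untested.

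Muscle genes were lower in the libraries labelled KO in both media, with Mapk14 RNA not lower. The choice among scalings was argued against, as at least 32 of 39 sarcomere members fell in KO DM against WT DM under the 3 other scalings. Total counts alone shifted these changes over all genes by a median of only 0.042, so a change of scaling could hardly have altered this. A smaller share of otherwise unchanged differentiated cells would lower the members alike only if the other cells held little of them, which was not measured. This was examined in the 36 members with the largest rises in WT DM against WT GM. Of these, 52.8% (19) lay within 2 SE of their median of -1.52, between the bounds set. A further test, added because of that, found deviations of 15.3 per degree of freedom, with Myh8 at -4.71 ± 0.30. These deviations argue against an equal loss, but they do not decide on a smaller share of differentiated cells. A difference between cell populations other than loss of Mapk14 may contribute: 19 genes on 11 chromosomes had at least 10 counts in every WT library and at most 3 in all KO-labelled libraries together, and 1 gene, Isl1, the reverse (both chosen after their values were seen). It cannot be told apart from an effect of the knockout, because the labels do not say how many clones were used, and the genotype stays open as an explanation.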
